A study of Rattus norvegicus with 6 samples.

How the data were processed

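Total RNA from rat hippocampus was profiled for long non-coding RNA (lncRNA) by sequencing. The samples were 3 libraries of 2VO rats given sterile water and 3 libraries of 2VO rats given trimethylamine N-oxide (TMAO) at 120 mg/kg, both for 8 weeks. Groups and replicate numbers came from the sample labels. Nothing in the labels says whether each library is a separate animal, so p-values measure the spread between these libraries.

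The authors deposited a table of 4972 lncRNA transcripts with raw read counts for each library, per the file headers. The same table gave FPKM values, made by the authors and rounded to 2 decimals, with a group mean in which 0 was written as 0.001. It also held the authors' log2 ratio of the group means, which recomputation from the deposited means gave back to within rounding error. The authors' p-value and false discovery rate stood beside it, and the test behind them is not given in the sources used here. A second deposited table listed 56 of these transcripts. They were exactly those with an authors' unadjusted p-value under 0.05 and an absolute log2 ratio above 1, and 20 had a source gene whose relation to the transcript is not stated. Per the submitters' processing notes, the tools were fastp 0.18.0, Bowtie2, HISAT2 2.1.0, StringTie and DESeq2 with the build rn6. The role of each tool, the strand setting and the counting method are not given in the sources used here. How reads were divided between overlapping transcripts of a locus is therefore unknown, and counts of single isoforms carry that uncertainty.

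Of the 4972 transcripts, 4083 had an Ensembl transcript identifier and 889 were assembled transcripts in 726 loci. A name other than an identifier was given for 345, of which 235 were accession-style and 110 carried 40 gene symbols. By symbol, 36 of the 40 were found in the RefSeq gene table for assembly GRCr8, 33 of them as protein-coding genes. None of the Ensembl transcript identifiers was found there, and no coordinates were printed because the builds differ.

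Counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization) in R 4.3.3. The low-count filter filterByExpr, with a minimum count of 10 and a minimum total of 15, left 1389 transcripts. The model held the group alone, and p-values were adjusted by the Benjamini-Hochberg method over all transcripts tested. The standard error (SE) of a log2 fold change was its absolute value over the square root of the F statistic. CPM values used TMM effective library sizes. For transcripts below the filter, fitted values came from the same model without the filter. Ratios of few counts had exact (Clopper-Pearson) binomial intervals at the 95% level, which cover counting error only. Where a group had no count, a floor of 3 counts over the group was used, equal to 1.13 CPM in 2VO and 1.15 CPM in TMAO. Single values were compared by two-sided exact permutation tests, in which 3 libraries against 3 cannot give a p below 0.1.

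Total counts in the table ran from 832233 to 919024 per library. The ratio of count to FPKM in 223 transcripts above 5 FPKM gave the relative depth of the whole libraries, from 0.941 to 1.08 with the 2VO-1 library as 1. Chi-square statistics per degree of freedom between libraries of a group ran from 12.7 to 17.8, so no pair was a repeat of one library.

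Alternatives fixed before the data were examined were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, no low-count filter, and a mean count of at least 50. Others were limma 3.58.1 on log2(FPKM + 0.1), with pseudocounts of 0.01 and 1 as well, the replicate number as a block, sums per locus, and each library left out in turn. The limma fits kept transcripts at 0.1 FPKM or more in at least 3 libraries. Whole-library sizes, a legacy edgeR estimate with robust priors, and DESeq2 with each library left out were added after the data were seen. On simulated counts for the 1389 transcripts, with 200 changed in each of 5 runs, the edgeR test recovered 26.8% of 2-fold and 71.2% of 4-fold changes, and 3.92% of its calls were false. DESeq2 recovered 39.6% and 76.2%, with 7.51% of calls false. The simulated counts were independent between transcripts, with no structure of the libraries beyond the group, and the share changed was set. These rates therefore need not hold for the calls in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

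The rule for named transcripts was also fixed before the data were examined. It took up to 12 per direction past an adjusted p of 0.05. Where fewer passed, it took up to 8 with a symbol, an unadjusted p under 0.05 and at least a 2-fold difference. It added all Fendrr transcripts, members of the fixed lists, the 5 most abundant transcripts, and the 5 with a symbol and the smallest p per direction in the authors' deposited table. After the values were seen, a symbol was read as the transcript's own symbol or its deposited source gene, since few transcripts had their own. Transcripts without a symbol were limited to 2 per direction, taken by smallest edgeR p, which was also settled after the values were seen. Of 9 lists of lncRNAs fixed beforehand, 7 had no symbol matched in the table: inflammation and stress, neuronal, small nucleolar RNA host, microRNA host, imprinted, neighbouring brain region, and X-inactivation lncRNAs. The study lncRNA and the vascular lists were matched by Fendrr alone, so no list test was possible, and members listed without a symbol would not have been found.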

Results

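Long non-coding RNAs were measured in the hippocampus of rats with 2VO, the vascular dementia model of the series title. The comparison asked which lncRNAs differed when such rats received TMAO, a metabolite that forms in the liver from trimethylamine made by gut bacteria. There were 3 libraries from 2VO rats given sterile water and 3 from 2VO rats given TMAO at 120 mg/kg for 8 weeks. Total lncRNA counts were 919024, 901380 and 914741 in the 2VO libraries and 883265, 838214 and 832233 in the TMAO libraries. Of 4972 transcripts listed, 2995 had a count in at least 1 library.

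No lncRNA passed an adjusted p of 0.05 between TMAO and 2VO in the edgeR quasi-likelihood test of 1389 transcripts, in which the smallest adjusted p was 0.188. Without adjustment, 105 transcripts had a p under 0.05, 42 higher and 63 lower in TMAO, where chance alone would give 69.45. The excess depended on the fit: 144 against 149.75 without the low-count filter, 63 against 39.15 at a mean count of at least 50, and 81 against 69.45 with DESeq2. With limma at pseudocounts of 0.1, 0.01 and 1 the counts were 129, 127 and 137 against 89.25. With a library left out in edgeR they were 84 to 113 against 72.55 to 73.25. Of the 105, 35 differed at least 2-fold, 10 higher and 25 lower. DESeq2, run as a second test, called 17 transcripts at an adjusted p under 0.05, 7 higher and 10 lower, and all 17 were among the 105. The values of the 3 TMAO libraries lay wholly on 1 side of the 2VO values for 16 of those 17, and for 14.4% of all tested transcripts, against 10% by chance. The 17 were called on these same values, which favours such separation, so the 16 are not independent evidence for the calls. The list of 35 became 45, 54 and 52 without 2VO-1, 2VO-2 and 2VO-3, and its share of higher transcripts, 28.6%, became 55.6%, 40.7% and 48.1%. With a TMAO library left out the share was 29.5% to 34.9%.

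**Figure D1:**
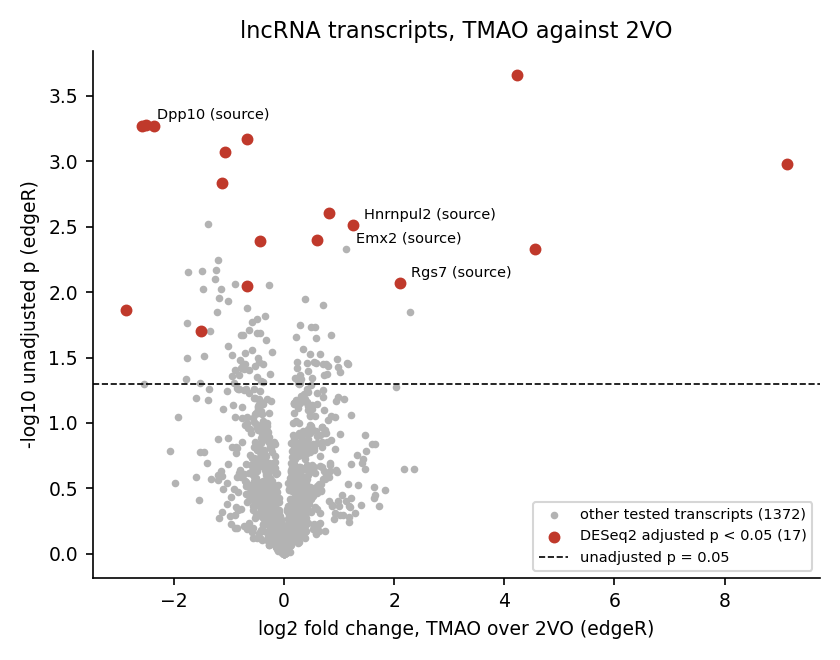
Log2 fold change of TMAO over 2VO against the negative log10 of the unadjusted edgeR p for each of 1389 lncRNA transcripts. Red points are the 17 transcripts with a DESeq2 adjusted p under 0.05, the dashed line marks an unadjusted p of 0.05, labels give deposited source genes, and no point passed an adjusted p of 0.05 in edgeR.

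Among tested transcripts lower in TMAO, the smallest p belonged to MSTRG.4686.5, whose source gene Dpp10 encodes an auxiliary subunit of Kv4 potassium channels. It measured 171 ± 65.3 CPM in 2VO and 30.1 ± 12.6 CPM in TMAO (SD, n = 3), 5.67-fold lower, with a log2 fold change of -2.50 (SE 0.40). Its adjusted p was 0.188 in edgeR and 1.37e-05 in DESeq2. A pair of assembled transcripts with no symbol had similar values: MSTRG.4699.1 was 5.13-fold lower (196, 187 and 299 counts against 59, 23 and 49), and MSTRG.4702.1 was 5.95-fold lower (78.9 ± 33.0 against 13.2 ± 4.21 CPM, SD, n = 3). Both had an adjusted p of 0.188 in edgeR, and of 2.01e-06 and 0.000397 in DESeq2. MSTRG.4261.1, with the source gene RGD1563400, was 2.76-fold lower (60.3 ± 30.2 against 21.7 ± 3.71 CPM), at an edgeR adjusted p of 0.503.

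Of transcripts higher in TMAO, ENSRNOT00000103001 has the source gene Hnrnpul2, which encodes an RNA-binding nuclear protein. It measured 243 ± 65.5 CPM in 2VO and 583 ± 161 CPM in TMAO (SD, n = 3), 2.40-fold higher, with adjusted p of 0.391 in edgeR and 0.00287 in DESeq2. MSTRG.5038.1, with the source gene Rgs7, a regulator of G protein signalling in neurons, was 4.32-fold higher at 46.7 ± 4.28 against 202 ± 125 CPM. Its adjusted p was 0.503 in edgeR and 0.0198 in DESeq2, and 0.0268 in edgeR without TMAO-2, whose count of 49 lay near the 2VO counts of 43, 37 and 44. DESeq2 also called it, at an adjusted p of 0.0457, in a split of 2VO-1, 2VO-2 and TMAO-2 against the rest. MSTRG.2178.1, with the source gene Emx2, a transcription factor of forebrain development, was 2.18-fold higher (41.7 ± 10.3 against 91.1 ± 21.6 CPM) and passed neither edgeR, at an adjusted p of 0.435, nor DESeq2, at 0.192. MSTRG.16406.11, with the source gene AABR07066700.1, was 4.86-fold higher at adjusted p of 0.584 in edgeR and 0.194 in DESeq2, and its groups overlapped. Its log2 fold change of 2.28 ran from 1.96 (without TMAO-3) to 2.97 (without 2VO-2) with a library left out. ENSRNOT00000102708, which has no symbol, had counts of 2, 3 and 1 in 2VO and 30, 27 and 58 in TMAO, 18.7-fold higher at adjusted p of 0.188 in edgeR and 0.000239 in DESeq2. MSTRG.429.1 had no count in 2VO and 119, 70 and 23 counts in TMAO, at least 72.0-fold higher against a floor of 3 counts over the 2VO group. Its adjusted p was 0.207 in edgeR, 1.27e-06 in DESeq2, and 0.0185 and 0.00324 with limma at pseudocounts of 0.1 and 0.01. With limma at a pseudocount of 1 the adjusted p was 0.235, so the limma call depended on the pseudocount.

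**Figure D2:**
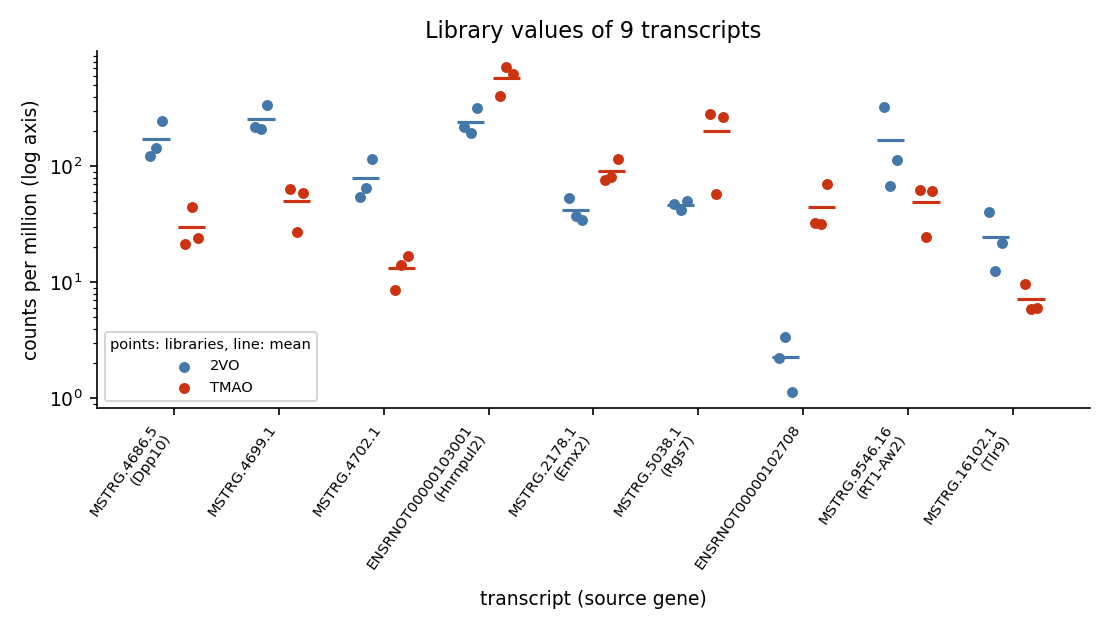
CPM on a log axis for 9 transcripts, with the deposited source gene in brackets. Points are the 3 libraries of each group and lines their means. In each transcript shown all 3 TMAO values lay on 1 side of the 2VO values, and none passed an adjusted p of 0.05 in edgeR. The 9 were chosen from the named transcripts, so their separation is not independent evidence. MSTRG.16406.11, whose groups overlapped, is not shown.

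Fendrr, the lncRNA of the series title, is transcribed beside the Foxf1 gene and acts in development of the mesoderm. It was chosen by the study on these samples, so its direction is not independent evidence. All 5 of its transcripts lay below the low-count filter. Fendrr-204 (ENSRNOT00000118749, with the deposited source gene Foxf1) had counts of 1, 0 and 0 in 2VO and 15, 1 and 5 in TMAO. The ratio of TMAO to 2VO was 21.4, with a 95% exact interval of 3.44 to 885, and the exact permutation p was 0.1 on CPM, the smallest possible, and 0.2 on raw counts, where 2VO-1 and TMAO-2 tie at 1. TMAO-1 held 71.4% of the TMAO counts, and without it the ratio was 9.48 (1.15 to 436). Both intervals cover counting error only, not the spread between libraries, so their exclusion of 1 does not by itself show a group difference. The edgeR fit without the filter gave an unadjusted p of 0.0202. This p rose above 0.05 without TMAO-1, 2VO-2 or 2VO-3, and stayed below it without 2VO-1, TMAO-2 or TMAO-3. With limma it was above 0.05 at each pseudocount, and with DESeq2 below. In the authors' deposited expression table this transcript had a log2 ratio of 3.50, an authors' unadjusted p of 0.0311 and a false discovery rate of 1.00. It was among the 56 transcripts of the second deposited table, which were chosen by unadjusted p and log2 ratio. Fendrr-203 had 9 counts in 2VO and 3 in TMAO, Fendrr-201 had 5 in each group and Fendrr-205 had 6 in each. Fendrr-202 had no count in any library, where a floor of 3 counts over all 6 libraries is 0.570 CPM. Summed over the 5 transcripts, Fendrr had 7, 11 and 3 counts in 2VO and 19, 5 and 11 in TMAO, a ratio of 1.70 (0.961 to 3.07) with an exact permutation p of 0.4. The interval included 1 and the library sums overlapped, so a difference in the sum was not detectable with these counts and libraries.

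**Figure D3:**
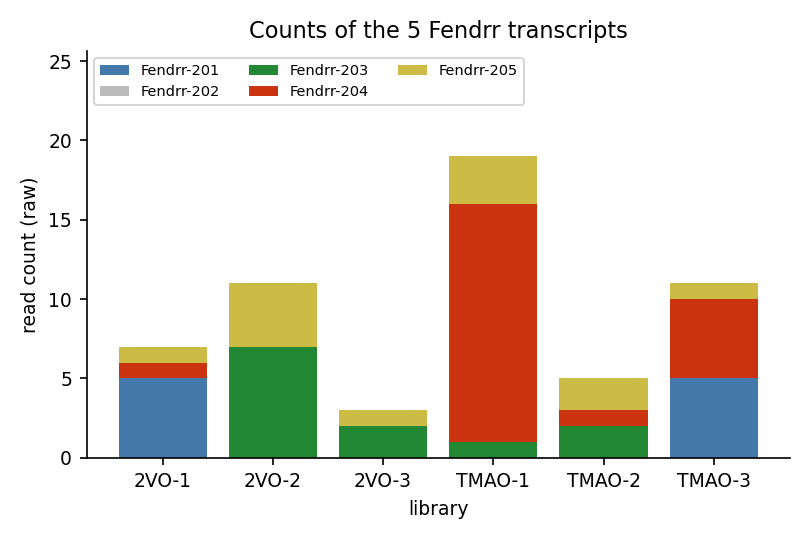
Raw read counts of the 5 Fendrr transcripts, stacked by library, for 3 libraries of 2VO and 3 of TMAO. Fendrr-204 made up 15 of the 19 counts in TMAO-1, Fendrr-202 had none, and the library totals of the groups overlapped.

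A set of 5 transcripts with an immune source gene was lower in TMAO by the means. Of the 5, 2 were in the edgeR test and neither passed, and 3 lay below the filter. They were brought together after their values were seen, from the deposited list of 56 transcripts that the authors chose by p and fold on these libraries, so their shared direction is not independent evidence. Of those tested, MSTRG.9546.16, with the class I histocompatibility gene RT1-Aw2, was 3.39-fold lower (168 ± 136 against 49.6 ± 21.6 CPM, SD, n = 3) at an edgeR adjusted p of 0.636. MSTRG.16102.1, with Tlr9, a receptor for unmethylated DNA, was 3.38-fold lower (24.7 ± 14.0 against 7.20 ± 2.17 CPM) at an edgeR adjusted p of 0.603. Without 2VO-1 their log2 fold changes of -1.76 each were -0.88 and -1.22. MSTRG.2983.2, with the chemokine Ccl5, had 55, 5 and 14 counts in 2VO and 1, 2 and 1 in TMAO. Transcripts with the immunoglobulin segments IGHV4-59 and IGKV1-16 had 25 and 206 counts in 2VO against 0 and 7 in TMAO. For the latter, edgeR without the filter gave an adjusted p of 0.761, and the alternatives gave 0.0499 (replicate number as a block) to 0.999 (DESeq2). The 2VO-1 library held 44% to 83.5% of each transcript's 2VO counts. For the IGHV4-59 transcript, with 11, 0 and 14 counts in 2VO, 2VO-3 was highest, and for the others 2VO-1 was. The 2VO-1 library was also highest for ENSRNOT00000100914, with the source gene Cd34, a surface protein of endothelial and blood-forming cells, which was picked after its values were seen. That transcript had 257, 97 and 126 counts in 2VO and 95, 63 and 85 in TMAO, at an edgeR adjusted p of 0.642. Summed, the 5 gave 627, 87.2 and 205 CPM in the 2VO libraries and 80.9, 32.8 and 68.8 CPM in the TMAO libraries.

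None of the 5 lncRNAs with the highest mean read count passed the edgeR or the DESeq2 test. Abundance by FPKM gives another order: MSTRG.13744.1, at 792 FPKM in 2VO and 558 in TMAO, lay above MSTRG.1744.7, at 333 and 291. It had an adjusted p of 0.435 in edgeR and 0.0323 in DESeq2. MSTRG.15949.1 was the most abundant, at 17.6 ± 2.24% of the counts in 2VO and 14.5 ± 0.93% in TMAO (SD, n = 3), with an exact permutation p of 0.2. On the CPM scale it was 1.27-fold lower in TMAO, at an edgeR adjusted p of 0.603. MSTRG.7914.2 had a log2 fold change of -0.21 (edgeR adjusted p 0.636), MSTRG.1744.7 of -0.13, MSTRG.4097.2 of -0.04 and ENSRNOT00000118194 of 0.04. The sign for ENSRNOT00000118194 turned with whole-library sizes and with limma on FPKM, and those for MSTRG.4097.2 and MSTRG.1744.7 without TMAO-3 and TMAO-1. Assembled transcripts held 78.2 ± 0.66% of the counts in 2VO and 76.5 ± 0.59% in TMAO (SD, n = 3), with an exact permutation p of 0.1. This difference of -1.75 percentage points was -0.59 in FPKM.

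In the authors' deposited expression table, 13 transcripts had a false discovery rate under 0.05, 8 higher and 5 lower in TMAO, and 12 of them were among the 17 called by DESeq2 here. The remaining transcript, MSTRG.12272.1, lay below the low-count filter and so was not tested in the main fits. The second deposited table listed 56 transcripts, 19 higher and 37 lower, of which 10 had a false discovery rate under 0.05 and 33 passed the low-count filter. All 33 had the same direction in edgeR, 31 had an unadjusted p under 0.05, and 0 passed the adjusted threshold, against 12 in DESeq2. The authors' values and the fits here rest on the same counts, and the 56 were chosen by p and fold on them. These overlaps are therefore not independent evidence. Acvr2a, an activin receptor, is the source gene of ENSRNOT00000110981, which had 0, 1 and 0 counts in 2VO and 0, 43 and 14 in TMAO. ENSRNOT00000115542, a transcript of Sumo3, had 16, 0 and 14 counts in 2VO and none in TMAO, with an exact permutation p of 0.4. Other Sumo3 transcripts were not all lower: ENSRNOT00000094434 and ENSRNOT00000118151 were 1.36-fold and 1.37-fold higher in TMAO, at unadjusted edgeR p of 0.328 and 0.326. Among transcripts that carry the symbol of a protein-coding gene, 52 were tested and 0 had an unadjusted p under 0.05 in edgeR.

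A one-sided test of whether the libraries separated by group could reach a p of 0.1 at the smallest. The mean Spearman correlation across transcripts was 0.915 within groups and 0.908 between them, a difference of 0.0066 with a one-sided exact permutation p of 0.2. It was 0.0086, at the smallest p of 0.1, for transcripts at a mean count of at least 50 (exact permutation), and 0.0038 at an exact permutation p of 0.2 with Pearson correlation of log2 values. On the first principal component, with 27.4% of the variance, 2VO-1, 2VO-2 and TMAO-2 lay apart from 2VO-3, TMAO-1 and TMAO-3. The labels name no factor that divides the libraries in this way. On the second, with 20.8%, the groups lay apart: the 2VO libraries were at 15.1, -1.46 and 12.5 and the TMAO libraries at -3.56, -17.3 and -5.32. The separation on the second component was not tested.

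**Figure D4:**
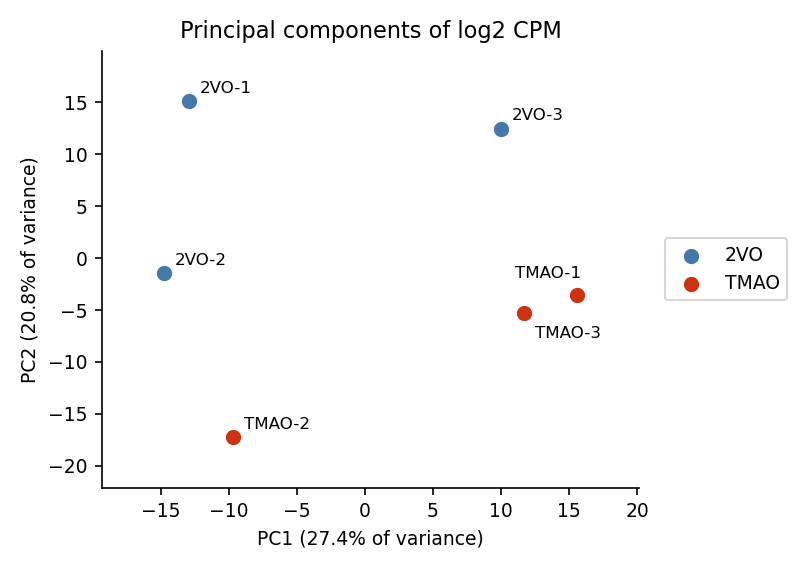
First and second principal components of log2 CPM for the 6 libraries, with the share of variance on each axis. The first component (27.4%) set 2VO-1, 2VO-2 and TMAO-2 apart from the other 3 libraries, across the groups. On the second (20.8%) every 2VO library lay above every TMAO library.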

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

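Whole-library sizes and the legacy edgeR estimate were chosen after the data were seen. The count of lncRNAs past an adjusted p of 0.05 was 0 in edgeR and 17 in DESeq2. With limma it was 2, 2 and 0 at pseudocounts of 0.1, 0.01 and 1, and in edgeR with a library left out it was 0 to 1. The 1 was the Rgs7-source transcript, without TMAO-2. DESeq2 with a library left out, also added later, called 12 to 18, of which 8 to 12 were among the 17. The cause of the difference between the tools was not tested. The list at an unadjusted p under 0.05 and at least 2-fold held 35. It held 86 without the filter, where 2995 transcripts were tested, and 11 at a mean count of at least 50, where 783 were. It held 58, 65 and 11 with limma at pseudocounts of 0.1, 0.01 and 1, and 43 to 54 with a library left out. Its share of higher transcripts, 28.6%, was 38.4% without the filter, 45.5% with limma at a pseudocount of 1, and 55.6%, 40.7% and 48.1% without 2VO-1, 2VO-2 and 2VO-3. The fitted log2 fold change of Fendrr-204 was 3.96. It was 0.84, 2.30 and 0.14 with limma at pseudocounts of 0.1, 0.01 and 1, 0.73 for the sum over Fendrr, and 2.85 (without TMAO-1) to 5.81 (without 2VO-1) with a library left out; a larger pseudocount shrinks a low value by construction.

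The replicate number as a block left 0 calls and 32 on the looser list, and turned no direction among the 35 transcripts followed below. The deviations of same-numbered libraries correlated at -0.05, 0.20 and 0.04 across transcripts, and the numbers were not read as pairs. Without the filter the block put the IGKV1-16 transcript at an adjusted p of 0.0499 in edgeR. The difference in assembled share, -1.75, was -0.59 in FPKM, -0.78 without the 10 most abundant transcripts, and -2.12 to -1.49 with a library left out. The overlap with the authors' table was 0 at the adjusted and 31 at the unadjusted threshold. Of 35 transcripts followed through the alternatives, 29 changed direction in none. Most of the 35 were picked for a small p or a large difference on these same libraries. That choice favours a kept direction, so the 29 are not independent evidence of stability. Those that changed direction were all Fendrr transcripts or among the most abundant, which were not picked for a difference. The 35 included all 17 DESeq2 calls, some of them not named here, and left out Fendrr-204, which is given above. ENSRNOT00000118194 went from 0.037 to -0.030 with limma at each pseudocount and to -0.031 with whole-library sizes, and Fendrr-205 from 0.034 to -0.052 with whole-library sizes. With a library left out, Fendrr-203 ran from -2.32 to 0.026, Fendrr-201 from -3.81 to 3.88, Fendrr-205 from -0.31 to 0.94, MSTRG.4097.2 from -0.10 to 0.042, and MSTRG.1744.7 from -0.22 to 0.044; the cause was not tested. Quantile normalization and limma without the trend were planned for tables without counts and were not run. Depth limits Fendrr, at 56 counts over 6 libraries.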

Other observations

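The tests of abundance, isoforms, immune source genes and locus numbers, and the count over other splits at an unadjusted p, were chosen after the values were seen; the other counts over splits and the first length test were set before their values were seen.

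Transcripts with no count in 1 group ran in both directions. There were 16 with no count in 2VO and counts in all 3 TMAO libraries, and 13 with the reverse. Of these, only MSTRG.429.1 passed the low-count filter. MSTRG.12272.1, below the filter, had 18, 9 and 22 counts in TMAO and an authors' false discovery rate of 0.0117. The edgeR fit without the filter called 0 transcripts at an adjusted p under 0.05. Most of the others had few counts per library in the group where they were counted, so no count in the other group does not show absence. Among the 20 transcripts with a source gene in the authors' list of 56, 9 were higher and 11 lower in TMAO. MSTRG.10150.8, with the source gene Fnbp1, had 43, 63 and 46 counts in 2VO and 2, 23 and 0 in TMAO. It passed neither edgeR, at an unadjusted p of 0.0502 and an adjusted p of 0.657, nor DESeq2, at an adjusted p of 0.588.

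The 3 transcripts at lowest p among those lower in TMAO, MSTRG.4686.5 (source gene Dpp10), MSTRG.4699.1 and MSTRG.4702.1, have close locus numbers. Summed, they gave 507 ± 171 CPM in 2VO and 93.2 ± 7.34 CPM in TMAO (SD, n = 3). Among 13 assembled loci called by DESeq2, 3 pairs lay within 20 locus numbers, against a mean of 0.238 in 10000 random draws from 634 tested loci (permutation p 0.0063). The split of 2VO-1, 2VO-2 and TMAO-2 against the rest, which crosses the groups, gave 3 such pairs among 10 loci (mean 0.134, permutation p 0.0020), with 7 of its 19 DESeq2 calls in 3 such loci. Calls at close locus numbers thus also arose in a split that is not the treatment. The distance of 20 and the 3 transcripts were picked after they were seen, so the first p overstates the evidence, and the identifiers give no positions.

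With 10 splits of the 6 libraries, no count can reach a share under 0.05. DESeq2 called 17 transcripts in the real split and 19 in the highest other, so 2 of 10 splits gave as many. The looser edgeR list held 35 in the real split and 38 in the highest other, again 2 of 10. At an unadjusted p under 0.05 alone edgeR had 105 in the real split and 87 in the highest other, so 1 of 10 splits, the real one, gave as many. The split with most DESeq2 calls among the others set 2VO-1, 2VO-2 and TMAO-2 against the rest, as the first principal component did. There edgeR made 8 calls at an adjusted p under 0.05, against 0 in the real split, and 2 of the 19 DESeq2 calls were shared with the 17. That split was picked as the highest of 9, and the component rests on the same values, so a structure of the samples that the labels do not name stays a hypothesis.

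MSTRG.429.1, with no count in 2VO and 212 in TMAO, belongs to a locus with 2 other listed transcripts. A candidate explanation is that reads were assigned to different isoforms of 1 locus in the 2 groups. The locus sum had a log2 fold change of 0.27 (SE 0.14), and MSTRG.429.1 held 1.10% of the locus counts in TMAO. At that share the sum would hardly move whether reads were reassigned or the transcript was newly made, so the 2 cannot be told apart. The main isoform, MSTRG.429.4, had 4178, 5668 and 5705 counts in 2VO and 7144, 5659 and 5541 in TMAO, and a switch of isoforms by TMAO stays open.

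The lower values of the immune source-gene transcripts may come from 1 library with more blood or immune cells, 2VO-1, which was also highest for the Cd34-source transcript. Without it the log2 ratio of the summed CPM was -1.27 (SE 0.74), against -2.33 with it, and each of the 5 members was still lower. The bound for this test was -0.5, and the value lay beyond it by less than 2 SE, a condition added after the value was seen. The members were picked for being lower on these libraries, which favours their staying lower, so the library and the treatment cannot be told apart. An effect of TMAO stays open and untested.

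Short transcripts were first thought to be lower in TMAO, as differing recovery by length would give. Across 1370 transcripts the Spearman rho of relative length and log2 fold change was -0.055, where a rho above 0.1 was required and the highest absolute value in other splits was 0.175, which argues against it. The pattern was then reworded, after that value was seen, to the 12 transcripts at a mean of 300 FPKM or more, of which 9 were lower (median log2 fold change -0.09). Of the 12, 9 were among the shortest 10%, whose other 128 transcripts had a median of 0.0086 (bootstrap interval over transcripts -0.091 to 0.053), too wide to settle whether they shared the lower values. With whole-library sizes the median of the 12 was -0.16, but that of all tested transcripts moved to -0.068 as well, so length for these transcripts, scaling and a difference by TMAO all stay open.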
